A study of Homo sapiens with 4 samples.

How the data were processed

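RNA sequencing was deposited for 4 samples of U937 macrophages, 1 per group: M1 and M2 macrophages, each untreated or exposed to MSC exosomes. Libraries were prepared from total RNA with a kit for Illumina sequencing, per the labels. The submitters' processing notes name STAR 2.6.1 and hg38 for all samples, while the headers of the M2 tables name HISAT2 alignments, each of a pair of input data sets. The version of HISAT2, the counting program, the strand use and any filter on the M1 lists are not stated.

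The M2 values are raw read counts per NCBI gene, per the file headers, as whole numbers with no normalization. The M1 column is named total counts in the deposited tables, but it holds another unit: whole numbers of 12 to 17 digits whose decimal points were lost, for listed genes only. Before the data were examined the design had assumed that each table would hold counts or an ordinary normalized unit for every gene, and the M1 tables did not. The digits of values shared by several genes lay on a lattice that fits the sum over 2 libraries of CPM plus 0.0001 each. From this, library totals and whole read numbers were restored for genes whose digits fit at 1 decimal place only, with a largest error of 8.98e-12. That gave 609 genes in the exposed and 890 in the untreated sample; all other M1 values were left out because their decimal place is unknown. On simulated tables of the same size the method restored 650 of 650 and 865 of 865 genes with whole read numbers, and 0 wrong values.

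The M2 tables hold 308382 reads (exposed) and 330403 reads (untreated), so a gene with 0 reads was set against a floor of 3 reads. That floor is 9.9 and 8.92 CPM on the TMM scale used within M2, and 9.73 and 9.08 CPM on the unscaled totals used against M1. M2 counts were scaled with TMM factors of 0.982 and 1.02 (edgeR 4.0.16) and expressed as CPM, reads scaled to a common library total. M1 values are the mean CPM of the 2 libraries, which the labels give as 1 sample; whether they are replicates is not given in the sources used here, and they were not used as such. M1 names were brought to current symbols, synonyms included, and genes whose deposited name is that of another gene model are not named in the text. Positions were taken from GENCODE release 29 on GRCh38.

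The 4 comparisons were exposed against untreated within M1 and within M2, and M2 against M1 among untreated and among exposed samples. With 1 sample per group no test across conditions is possible, so genes were counted past a fixed size of 2-fold on log2 ratios with a pseudocount of 1. Genes entered with at least 1 CPM and 10 reads in the higher library and a value in both tables. Exact conditional binomial (Clopper-Pearson) intervals at 95% were computed for ratios of reads without the pseudocount; they cover counting error only, since reads without molecular identifiers are not independent molecules. In M2, 2 reads were taken as 1 fragment for the intervals and for 200 simulations of unchanged genes. This is approximate, as 59.2% (exposed) and 59.8% (untreated) of counts from 1 to 10 were even. That choice, the intervals' use to name genes and the minimum of 30 reads were made after the data were seen.

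Genes were named by a rule written before the data were examined: the 12 protein-coding genes with the largest and the 12 with the smallest log2 ratio at 10 CPM or more in the higher library, up to 4 members of each described list with the largest absolute log2 ratio, and 12 polarization genes in every sample. Some genes that the rule takes are not reported here. Others are said to be chosen after their values were seen. The 34 gene lists were set apart from other genes by their median log2 ratio among 10000 random lists of the same size matched on expression, where at least 3 members were measured. Most of these lists had a median within the random range and are shown only in the plot of list medians.

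The comparison was tested on simulated M2 tables of 12935 genes with 200 changed genes: 47.8% of genes changed 2-fold, 89.6% of those changed 4-fold and 97.0% of those changed 8-fold were found past 2-fold in the right direction. Of 12736 unchanged genes 26.2% also passed 2-fold, and intervals covered the true ratio for 96.9% of 6073 genes. The simulated reads were drawn as fragments of 2 reads, as the intervals assume, so this coverage does not check that assumption. The alternatives tried were pseudocounts of 0.1 and 5, no minimum, a minimum of 10 CPM, median-of-ratios factors (DESeq2 1.42.0) and a common total. Added after the data were seen were a minimum of 30 reads, a correction over 20 bins of GC content, a total without small structural RNAs and mitochondrial genes, each M1 library alone, and the leaving out of renamed M1 genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3.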

Results

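The series measured RNA by sequencing in macrophages made from U937, an established human line of monocyte-like lymphoma cells. The cells were first differentiated with the phorbol ester TPA at 10 nM for 3 days and then given IFN-γ, for macrophages of the M1 type, or IL-4, for macrophages of the M2 type. Each type was measured untreated and after exposure to exosomes of bone marrow mesenchymal stromal cells (MSC); the design text describes this exposure as culture of both cell kinds on either side of a porous filter. The 4 samples form 4 groups of 1, so no difference below has a replicate check and no p-value is given. Differences are therefore described by a fixed size, a ratio of at least 2-fold after a pseudocount of 1 CPM (reads scaled to a common library total), and by intervals that cover counting error only.

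The depth differed strongly between the cell types. The M2 count tables held 308382 reads in the exposed sample and 330403 in the untreated one, over 28395 genes, with a median of 6 reads per gene in each, and 1 read was worth 3.24 and 3.03 CPM. The M1 tables list summed values whose decimal points were lost; values could be restored for 609 of 3139 listed names (19.4%) in the exposed sample and for 890 of 12233 (7.28%) in the untreated one. These restored values fit 2 libraries per sample, of 8399457 and 6004579 reads (exposed) and of 14111620 and 15343828 reads (untreated). The 2 libraries are not labelled and were treated as 1 sample, with their mean as its value.

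In M1 macrophages, where the question was what the exosomes change in inflammatory cells, most genes restored in both samples were far lower after exposure. S100A9, a calcium-binding alarmin of myeloid cells, stood at 4.15 CPM after exposure against 595 CPM untreated, 143-fold lower. CREG1, a lysosomal glycoprotein, stood at 1.55 against 275 CPM (177-fold lower), GHITM, a protein of the mitochondrial inner membrane, at 1.62 against 295 CPM (182-fold lower), and THBD, the thrombin receptor thrombomodulin, at 2.24 against 186 CPM (83.0-fold lower). The 2 exposed libraries stood at 0.595 and 2.498 CPM for CREG1 and at 1.07 and 2.17 CPM for GHITM. Others among the 12 protein-coding genes with the smallest ratios were MAPRE1, which binds microtubule ends, the linker histone H1-10, the proteasome subunit PSMB2, the repressor ZNF703 and the GTPase NRAS. These 12 genes ranged from 1.23 to 5.33 CPM in the exposed sample and from 132 to 595 CPM in the untreated one. The smallest restored exposed value of any gene was 1.04 CPM. Most of the 12 lay close to it, so the size and order of their ratios mostly follow the untreated level.

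Of the 152 genes restored in both M1 samples, 129 were at least 2-fold lower and 3 at least 2-fold higher after exposure, and the median log2 ratio was -3.97. In 141 of the 152, both exposed libraries lay below both untreated libraries. The mitochondrially encoded MT-ATP8 (4.11 against 346 CPM), MT-ND4L (5.33 against 369 CPM) and MT-ND3 (7.44 against 293 CPM), subunits of ATP synthase and of respiratory complex I, were lower, 3 of 3 restored members of that list. Centred on the median ratio of all restored genes their log2 ratios were -1.73, -1.46 and -0.67. The immediate early genes JUNB (3.06 against 176 CPM), DUSP1 (1.77 against 108 CPM) and EGR1 (1.31 against 7.88 CPM, with untreated libraries at 4.75 and 11.01 CPM), which answer to growth and stress signals, were lower in 3 of 3 as well. The median log2 ratio was -5.87 in the first list and -5.29 in the second; both lay within the central 95% of random lists matched on expression (-6.76 to -4.66 and -5.62 to -2.25), so neither list stood apart from other genes of like expression. Relative to the median ratio of all restored genes, JUNB and DUSP1 stayed below 0 on the log2 scale (-1.17 and -1.22) while EGR1 was above it (1.53); with a common total of the shared genes EGR1 was at 0.02.

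Among the 3 higher genes were MT-RNR1, the small ribosomal RNA of mitochondria (912 against 402 CPM), and MIR3648-1, a transcript of the ribosomal DNA repeat (18.3 against 1.55 CPM; 11.55 and 24.98 CPM in the exposed libraries, 1.98 and 1.11 CPM in the untreated ones); these were named after their values were seen, and the third, an RNA gene with a clone-based name, is not reported here. Among the 152 genes restored in both samples, no protein-coding gene was at least 2-fold higher. Genes restored in exposed M1 that the untreated list does not name, 157 of them protein-coding, could not enter this count. The 53 reads of S100A9 in the exposed libraries give a pooled ratio of 0.00629, with an exact 95% interval of 0.00471 to 0.00823, but the 2 exposed libraries themselves stood at 1.31 and 6.99 CPM. The split depends on scaling: centred on the median ratio, which shifts the median log2 ratio by 3.97, it was 53 higher and 38 lower, and scaled to a common total of the shared genes, a shift of 2.19, it was 17 higher and 94 lower. All values above are relative to library totals, of which the restored genes hold 0.277% (exposed) and 2.33% (untreated).

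**Figure D1:**
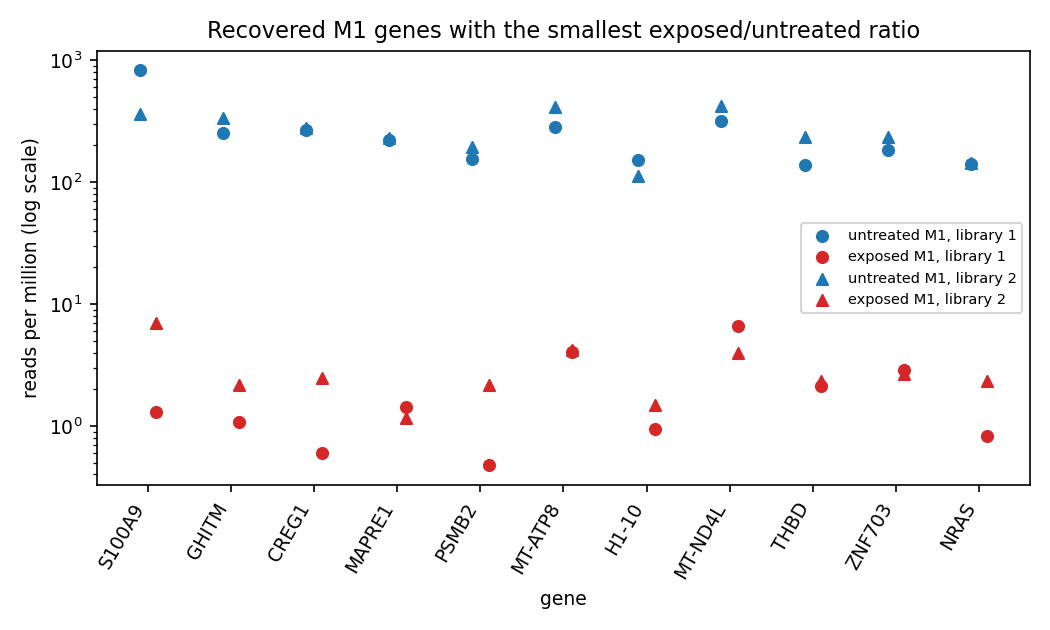
CPM (log axis) of 11 of the 12 protein-coding genes with the smallest exposed to untreated ratio in M1; each point is 1 of the 2 unlabelled libraries of a sample. Both exposed libraries lie below both untreated ones for each of these genes, with S100A9 at 1.31 and 6.99 CPM exposed against 824 and 365 CPM untreated.

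The names in the M1 lists need no restored value. The untreated list named 12233 genes and the exposed list 3139; 2448 names were in both. Of the ribosomal protein genes, 23 of 32 named untreated were also named exposed (71.9%, exact 95% interval 53.3 to 86.3) and 12 of 12 mitochondrially encoded genes. The share was 8 of 13 for MHC class I and antigen processing genes, 8 of 13 for heat shock genes, 11 of 20 for lysosomal genes and 10 of 20 for glycolytic genes. Over all untreated names the share was 20.01%. Of 31 nuclear-encoded genes of oxidative phosphorylation, 8 were named in both (25.8%, 11.9 to 44.6). Of interferon-γ response genes 3 of 17 were named in both (17.6%, 3.80 to 43.4), of type I interferon-stimulated genes 3 of 19, of inflammasome genes 3 of 18, and of metallothioneins 0 of 5. Low shares were not particular to inflammatory lists. They were 2 of 13 for IL-4 response and 3 of 17 for cell cycle genes, against 8 of 25 for inflammatory cytokine and 10 of 16 for housekeeping genes. The shares were not matched on untreated level, and no test compared one list with another.

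Among restored untreated genes that the exposed list does not name, CCL1, a monocyte-attracting chemokine, stood at 415 CPM, the lipopeptide receptor TLR2 at 151 CPM, the maturation marker CD83 at 134 CPM and the complement receptor C3AR1 at 132 CPM; these were picked after their values were seen. The 2 untreated libraries differed for CCL1, at 712 and 117 CPM, and for C3AR1, at 176 and 87.5 CPM. Whether a gene stayed listed followed its untreated level: 73 of 112 genes with a summed value of 100 CPM or more were named in the exposed list, against 15 of 244 below 5 CPM. The smallest restored sum in the exposed list was 2.07 CPM, so an unlisted gene is taken as low, not as absent.

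In M2 macrophages, where the question was what the exosomes change in IL-4-polarised cells, single genes stood far above their untreated level; these were named after the data were seen. FABP4, the fatty acid binding protein of macrophages and adipocytes (chromosome 8, 81478419 to 81483263 on GRCh38), had 105 reads exposed against 2 untreated, a ratio of 58.3 with an exact 95% interval of 10.0 to 2346. The lysosomal protease CTSD (chromosome 11, 1752752 to 1764573) had 137 against 37 reads, a ratio of 4.11 (2.43 to 7.29). The secreted phosphoprotein SPP1 (osteopontin) had a ratio of 4.78 (1.99 to 13.5), the cytokine TGFB1 one of 4.44 (2.05 to 10.8), and the phospholipid-binding ANXA1 one of 4.53 (1.88 to 12.8). Reads of the mitochondrially encoded genes were fewer after exposure, with 13 of 13 genes below their untreated level; reads of RNA and of mitochondrial DNA could not be set apart.

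Other genes with at least 30 reads and intervals far above 1 were RAB13 (6.77, 2.61 to 22.3), the surface peptidase ANPEP (4.26, 2.22 to 8.83), the intermediate filament gene VIM (3.97, 2.62 to 6.19), the ferritin light chain FTL (2.32, 1.94 to 2.79) and the actin crosslinker FLNA (2.23, 1.75 to 2.85). VIM overlaps VIM-AS1, which had 123 against 38 reads, and without stated strand use their reads cannot be told apart; FTL and RPS4X (5.15, 2.01 to 16.1) have processed pseudogenes whose reads could not be set apart. The ferritin heavy chain FTH1 lay on the other side of 1, with 295 against 540 reads and a ratio of 0.607 (0.493 to 0.744). Apart from mitochondrial genes, the lower protein-coding genes farthest from 1 were RD3 (34 reads untreated, 2 exposed), GRIPAP1 (34 and 5), TONSL (44 and 8) and RUSC1 (45 and 9). The genes named by this interval were chosen after the data were seen. In all, 124 genes with 30 or more reads had an interval above 1 and 110 one below 1, against 54.8 and 64.1 in simulations of counting error alone, whose highest values were 75 and 86. Such intervals compare 2 libraries, not the conditions.

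**Figure D2:**
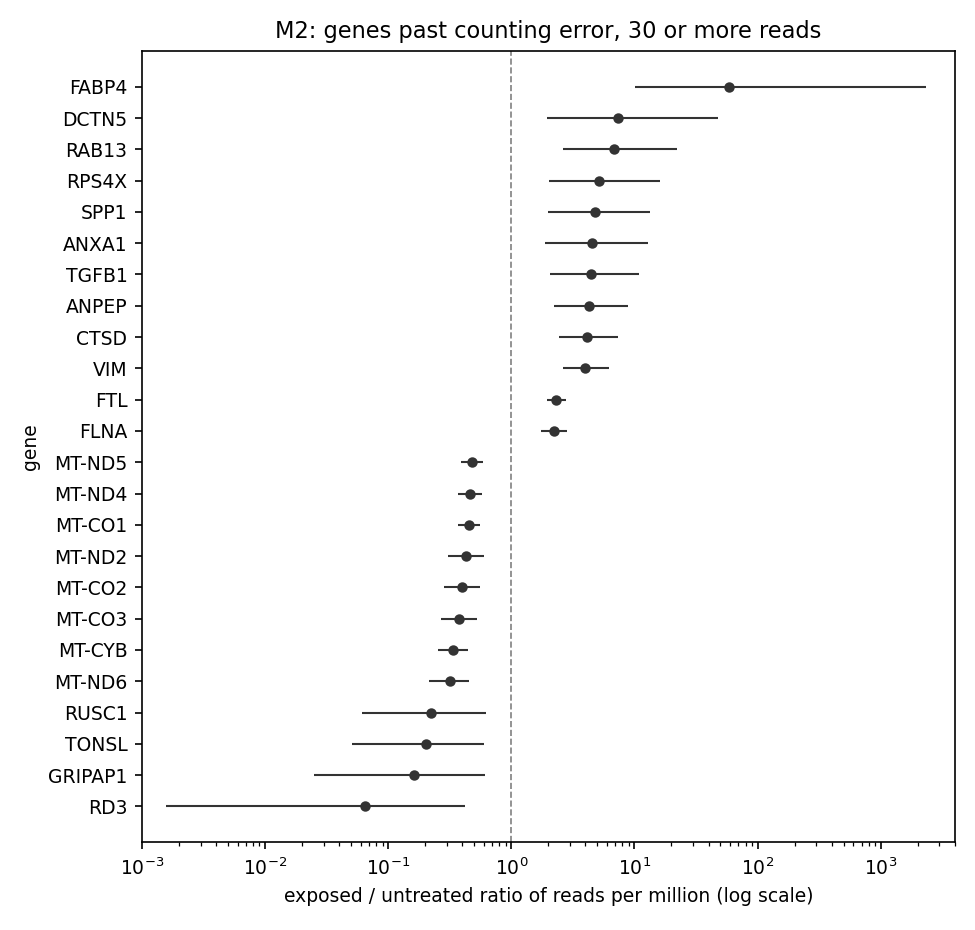
Ratio of CPM, exposed over untreated M2 (log axis), for the 12 protein-coding genes on each side whose interval lies farthest from 1 among genes with 30 or more reads; bars are exact 95% intervals of counting error, with 2 reads taken as 1 fragment. FABP4 has the highest ratio, 58.3, and 8 of the 12 lower genes are mitochondrially encoded.

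The 34 gene lists, fixed before the data were examined, gave 31 medians in M2, and 2 lay outside the central 95% of random lists, where chance gives 1.55. The mitochondrially encoded list had a median log2 ratio of -1.21 (random lists -0.31 to 0.41), with 11 of 13 genes at least 2-fold lower and a pooled ratio of 0.432 (0.397 to 0.469). MT-CO1, the core subunit of cytochrome oxidase, had 253 against 617 reads, MT-CYB 134 against 442 and MT-ND6 78 against 275. The immediate early list had a median of 0.57 (random lists -0.33 to 0.37), with 14 of 20 genes above 0, 3 at least 2-fold higher and 2 at least 2-fold lower. Its pooled ratio was 1.30 (1.07 to 1.57), and 1.21 (0.986 to 1.48) without JUN. JUN had 58 against 25 reads, a ratio of 2.58 (1.29 to 5.47), and ATF3 36 against 16, while NR4A1 went the other way with 6 against 31.

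Lists within the random range still held single genes past counting error. In the IL-4 response list 5 of 14 genes were at least 2-fold higher and the pooled ratio was 1.96 (1.499 to 2.57); it was 1.31 (0.979 to 1.77) when FABP4 was left out. IL1RN, the interleukin-1 receptor antagonist, was among them with 47 against 12 reads, a ratio of 4.35 (1.73 to 13.03), and IL4R, the IL-4 receptor chain kept in the list of scavenger and IL-10 genes, had 13 against 45 reads, a ratio of 0.321 (0.112 to 0.793). In the lipid handling list 6 of 15 genes were at least 2-fold higher, with the fatty acid binding protein FABP5 at 35 against 8 reads, the lipase LPL at 22 against 5 and the lipid droplet protein PLIN2 at 21 against 6; its median log2 ratio was 0.37 (random lists -0.46 to 0.45). The inflammatory cytokine list went both ways, with 4 of 15 genes higher and 4 lower: the chemokines CCL2 (34 against 8 reads) and CCL7 (19 against 2) were higher with intervals above 1, while IL12B (2 against 10) and PTGS2 (5 against 19) were lower with intervals that include 1.

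Of 29 ribosomal protein genes 21 lay above 0, with a pooled ratio of 1.31 (1.13 to 1.52) and a median within the random range. The lysosomal list had a pooled ratio of 1.5 (1.23 to 1.83), which was 1.195 (0.957 to 1.49) without CTSD. The type I interferon list had a median log2 ratio of -0.52 (random lists -0.72 to 0.54), with 4 of 16 genes lower, among them ISG15 at 4 against 13 reads (ratio 0.342, 0.0342 to 1.85). Markers of mesenchymal stromal cells, meant as a check for RNA of the other cell kind, had a median of -0.02 over 16 genes. Their pooled ratio was 1.08 (0.872 to 1.34). They had 345 reads exposed and 354 untreated. Since the untreated sample also held such reads, these values cannot show or exclude a small amount of stromal RNA.

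**Figure D3:**
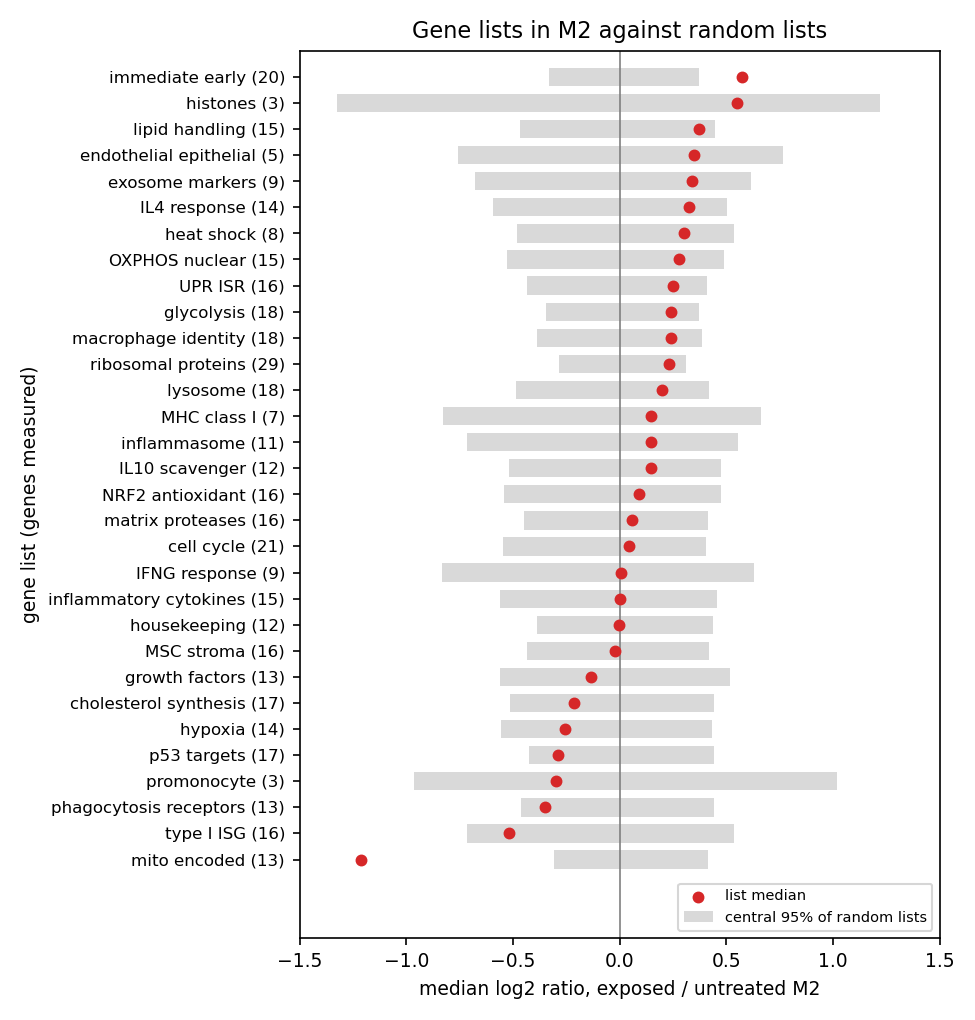
Median log2 ratio, exposed over untreated M2, of each gene list with 3 or more measured genes (points), beside the central 95% of 10000 random lists matched on expression (grey bars); the number of measured genes is in parentheses. The mitochondrially encoded list at -1.21 and the immediate early list at 0.57 lie outside their bars.

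Across 12653 genes in M2, 1548 were at least 2-fold higher and 1866 at least 2-fold lower after exposure, with a median log2 ratio of -0.05. Most of this could be counting error if 2 reads count as 1 fragment. With no change, splitting the same reads as fragments gave on average 1395 higher genes (1279 to 1477) and 1974 lower (1880 to 2090). The 1548 higher genes lay above that range and the 1866 lower ones below theirs, so the simulation only approximates the counting error. Splitting the reads singly gave 575 and 702. The choice of fragments was made after the data were seen. Among the 12 protein-coding genes with the largest ratios 11 had no read in the untreated sample. Of these, AK7 with 17 reads was 6.29-fold higher against a floor of 3 reads, and ENPP7 with 16 was 5.92-fold higher. All of the 12 with the smallest ratios had no read in the exposed sample, with SLC17A9 at 19 reads untreated (5.70-fold lower against that floor). Such floor values are not interval bounds. With 2 reads taken as 1 fragment, even RNU1-27P, at 57 untreated reads against 0, had a bound of 6.52-fold. At 30 or more reads, 169 of 1889 genes were higher and 201 lower, against 89.9 and 147 simulated, with highest simulated values of 118 and 183.

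The polarization genes were checked in every sample, and 11 are reported. None of the 11 had a restored value in M1; 4 were named in the untreated M1 list (CD86, CD163, CD209 and TGM2) and 0 in the exposed list. In M2 the exposed and untreated samples had 10 and 19 reads for MRC1, the mannose receptor, 15 and 10 for CD163, 2 and 9 for CD209, 10 and 14 for CCL22 and 10 and 18 for TGM2. CXCL10, IDO1, CD80, CD86, NOS2 and ARG1 had from 2 to 18 reads. The interval of the ratio included 1 for all 11 genes, so a shift between M1-type and M2-type markers was not detectable at this depth. Background reads may be a further limit. In M2, olfactory receptor genes had 48.3% (exposed) and 39.1% (untreated) of the mean reads per kb of protein-coding genes.

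The cell types were compared across tables that were normalized separately and made differently, so levels are only set side by side. Untreated M2 had no read for CCR1, a chemokine receptor, where untreated M1 stood at 105 CPM (11.6-fold lower at the floor of 3 reads). It had none for TNF, where M1 stood at 65.0 CPM (7.16-fold lower at that floor). These floor values are not interval bounds. TLR2 stood at 6.05 against 151 CPM and S100A9 at 45.4 against 595 CPM. The 3 measured inflammatory cytokine genes, TNF, CCL8 and CXCL5, had a median log2 ratio of -4.19, below the random range (-3.10 to 3.55). But 2 of them had no read in M2, and with these set at the floor of 3 reads the median was -0.93. Higher in M2 were SCUBE3, a secreted glycoprotein (466 against 1.99 CPM), and ARFGEF3 (197 against 2.71 CPM). Of 447 genes 169 were at least 2-fold higher in M2 and 127 lower; scaled to a common total the split was 119 and 232, and centred on the median ratio 128 and 209.

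In the exposed samples, M2 stood above M1 for nearly all genes that could be compared. Examples were MAVS, an adaptor of antiviral signalling (204 against 1.33 CPM), and TGFB1 (221 against 3.65 CPM, with M1 libraries at 2.14 and 5.16 CPM). The 4 mitochondrially encoded genes compared, among them MT-ND5 (856 against 68.0 CPM), had a median log2 ratio of 3.49, below that of random lists (4.21 to 5.73); it turned to -1.57 when centred on the median ratio and to -0.94 with a common total. Of 406 genes 390 were at least 2-fold higher in M2 and 16 lower, with a median log2 ratio of 4.47. All 16 lower genes stood under 10 CPM in exposed M1, about the M2 floor of 9.73 CPM for 3 reads. The depth of M2 therefore cannot show that they were lower. A gene enters with 10 reads in M2, 32.4 CPM, while the median restored value in exposed M1 was 1.39 CPM. Centred on the median ratio the split was 38 higher and 84 lower, and with a common total 132 and 46.

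Across the 117 genes that entered both exposure comparisons, the log2 ratios in M1 and M2 had a Pearson correlation of -0.12 and a Spearman correlation of -0.13; genes are not independent replicates, and the value describes these libraries. The direction was shared for 67 genes (57.3%). That share says little about agreement. Of the 152 M1 ratios 146 lay below 0, so it mostly follows the share of M2 genes below 0, which was 52.3% over all M2 genes. MT-ATP8 and MT-ND3 were at least 2-fold lower in both cell types as scaled here (MT-ND3 was at -0.67 in M1 when centred on the median ratio), as was the linker histone H1-10 (log2 ratios -5.90 and -1.92), whose interval in M2 includes 1; these were picked after their values were seen.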

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

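All tests in this part were chosen after the results were seen, and an earlier form of the GC correction had been tried on the same data.

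Opposite directions in M1 and M2 drew attention to 4 genes. The difference between the cell types was not tested. As 146 of the 152 M1 ratios lay below 0, a gene higher in M2 mostly counts as opposite. GHITM had a log2 ratio of -6.82 in M1 and 1.33 in M2, where its 14 against 6 reads leave an interval of 0.592 to 15.5. CREG1 had -6.76 in M1 and 2.58 in M2 (23 against 4 reads, interval 1.41 to 59.0). ZNF703 had -5.81 and 1.10 (39 against 20 reads, 0.963 to 5.20). MT-RNR1 had 1.18 and -0.80 (3106 against 6003 reads, 0.540 to 0.611). Centring M1 on its median ratio shifts the median of the M1 log2 ratios by 3.97. With 1 sample per group, no sample could be compared with others of its group.

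A signal outside the comparisons came from 266 restored genes of exposed M1 that the untreated list does not name. Among them were 157 protein-coding genes and 23 small structural RNAs, such as RNU4-2 at 70.4 CPM and RNU4-1 at 28.96 CPM.

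The first pattern weighed is the low level of restored genes in exposed M1. A choice of genes made by the restoring step is argued against as the whole cause if both lists keep genes above a like minimum (smallest restored sums 2.07 and 2.03): of 376 genes restored at a summed 20 CPM or more in the untreated sample, 66.0% (60.9 to 70.7) were not named in the exposed list at all. Dilution of every transcript by 1 common factor cannot cover MT-RNR1 (912 against 402 CPM) or MIR3648-1 (18.3 against 1.55 CPM), which were higher after exposure. For the lower genes such dilution stays open. In all, 138 of 152 exposed values lay under 3 times the smallest one (1.04 CPM), where ratios follow the untreated level. The log2 ratios of the other 14 genes, MT-RNR1 and MIR3648-1 included, had an interquartile range of 5.15 with a bootstrap interval of 0.42 to 9.01. Even background reads along exons stay open. Protein-coding genes listed in exposed M1 alone had 2.93 times the median exon length of genes in neither list (2.76 to 3.08). But those listed in untreated M1 alone had 1.54 times. Restored exposed values hardly followed exon length (Spearman 0.086 over 446 genes). That correlation cannot decide the question, because most restored exposed values lay near the smallest one. An effect of the exosomes also stays open, untested, since the exposure coincides with the library.

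The second pattern is the excess of 2-fold differences in M2 over counting of single reads. Counting both mates of a fragment as reads could account for part of it, with a variance 2.09 times that of single reads in 290 olfactory receptor genes (1.87 to 2.31). Not every read had a counted mate: of genes with 1 to 10 reads, 59.2% (exposed) and 59.8% (untreated) had an even number, and 1074 and 1013 genes had 1 read. GC content as the whole source is argued against: after its correction 343 genes with 30 or more reads still differed 2-fold, against 370 before and 198 to 287 in simulations of fragments. What remains beyond fragments may be library preparation or the exposure, which 1 sample per group cannot part.

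The third pattern is the lower mitochondrial counts in exposed M2. GC content is argued against by a median log2 ratio of -1.39 after its correction, with the 13 single genes from -1.86 to -0.82. Dilution of all cellular RNA is argued against by the pooled ratio of ribosomal protein transcripts, 1.31 (1.13 to 1.52). Mitochondrial DNA among the counted reads stays open. Reads per kb of MT-ND6, encoded on the other strand from most mitochondrial genes and usually a scarce transcript, were set against the other 12 genes. They were 1.51 times the median of those genes in the untreated sample and 1.08 times in the exposed one. This cannot decide the question: without stated strand use, RNA from the opposite strand would also count as MT-ND6. Whether the lower counts reflect less DNA, less RNA or both cannot be told, and an effect of the exosomes was not tested. Reads per kb of olfactory receptor genes, a measure of background, were not lower in the exposed sample (1.06 against 0.951). Those genes are nuclear, so they do not measure mitochondrial DNA.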

How the results depend on the processing

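The minimum of 30 reads, the GC correction, the total without small structural RNAs and mitochondrial genes, the use of single M1 libraries and the leaving out of renamed M1 genes were chosen after the data were seen. No paired analysis was possible because each group held 1 sample, and no result here has a test. Gene counts that moved by over 1.5 times did so mostly with scaling or with the minimum. With median-of-ratios factors M1 had 53 higher and 38 lower genes after exposure, untreated M2 had 209 genes lower than untreated M1, and exposed M2 had 38 higher and 84 lower than exposed M1. With a common total there were 17 higher genes in M1, 232 lower in untreated M2 and 132 higher and 46 lower in exposed M2. These follow from the shift of all ratios that each scaling makes. With no minimum M2 had 4461 higher and 4815 lower genes after exposure, untreated M2 had 277 higher than untreated M1, and the correlation of responses was -0.18. With 30 reads M2 had 169 and 201, as fewer genes enter, and the correlation was -0.24. The genes lower in exposed M2 than in exposed M1, 16 as reported, were 0 with a pseudocount of 5, 0 with a minimum of 10 CPM and 7 with the second M1 libraries. All 16 thus stood under 10 CPM in exposed M1, about the M2 floor of 9.73 CPM. Why the second libraries gave fewer was not tested. The mitochondrial list in exposed M2 against exposed M1 reversed to -1.57 (median of ratios) and -0.94 (common total). Without renamed M1 genes, M1 had 2 higher and 118 lower genes after exposure. The GC correction gave 1476 higher genes in M2, 1327 of them shared with 1548, and 1819 lower, 1640 of them shared with 1866. The depth of M2 limits most single genes: at a median of 6 reads a 2-fold difference is within counting error.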

Other observations

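No test in this part was planned; the values were looked up after the data were seen.

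Small structural RNAs took a large part of the M2 reads. RN7SL1 and RN7SL2, the RNA of the signal recognition particle, held 15.02% of reads in the exposed and 9.72% in the untreated sample, with a ratio of 1.67 (1.63 to 1.72) for RN7SL1. RPPH1, the RNA of ribonuclease P, had a ratio of 1.39 (1.30 to 1.49), the spliceosomal RNU2-2 had 115 against 16 reads and RNA5S9, a 5S ribosomal RNA, 74 against 18. Other copies went the other way, with 8 against 42 reads for the 5S gene RNA5S2, 0 against 57 for the U1 copy RNU1-27P and 2 against 45 for RNU1-28P. RMRP (0.829, 0.704 to 0.974) and SNORD3A (0.744, 0.614 to 0.899) lay below 1, and RNU4-2 was at 1.00 (0.773 to 1.29).

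Olfactory receptor genes, which macrophages are not known to express broadly, had 1.06 reads per kb in the exposed and 0.951 in the untreated M2 sample, 48.3% and 39.1% of the mean over all protein-coding genes. Reads followed exon length across protein-coding genes, with a Spearman correlation of 0.562 and 0.546; genes are not independent replicates. Stromal markers were rare in M1: COL1A2 and FBN1 were named in the exposed list alone, and COL6A3, ENG and ACTA2 in the untreated list alone.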
